A study of Homo sapiens with 12 samples.

How the data were processed

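RNA was measured by sequencing in 12 libraries from cultured human cells. MCF-10A, a non-tumorigenic breast epithelial line, and SK-BR-3, a breast cancer line with an amplified ERBB2 (HER2) gene, were each exposed for 16 h to 20 µM diallyl trisulfide (DATS), an organosulfur compound of garlic, or to the solvent dimethyl sulfoxide (DMSO, 0.07%). Per the labels' protocols each sample type was prepared independently 3 times, cells were detached with trypsin, and total RNA was purified on silica columns. Libraries were grouped by the cell line and treatment in their labels into 4 groups of 3.

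Reads were aligned with STAR 2.6.1d and compared with DESeq2 on GRCh38 (hg38), per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. The gene identifiers of all 58735 genes in the deposited table matched GENCODE release 29, and the lengths deposited for 6372 genes equalled the merged exon lengths of that release. The FPKM table deposited by the authors (fragments scaled to exon length and sequencing depth) holds a value for every gene and library, divided by an effective library size that differed from the read total by a factor of 0.886 to 1.07. A pair of further tables lists, per the file headers, whole read counts for the genes at an unadjusted p under 0.05 in each cell line. In those tables the authors also deposited a normalized signal per library, which equals the read count divided by 1 size factor per library. The log2 fold change in these tables is DATS over DMSO by the authors. The p-value columns, unadjusted and adjusted, are the authors' as well, per the file headers. Among the gene names deposited with the FPKM values, 27 had been turned into calendar dates, and those genes were followed by their identifiers.

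Multiplying each FPKM value by the gene length and by the library's effective size gave whole reads for 704820 of 704820 values, within a tolerance of 1e-06 read (largest gap 1.1e-09). Depth is therefore known: 15295046 to 18407213 reads in genes per library, with 21211 to 22380 genes having at least 1 read. The design fixed before the data were examined named limma on log2 FPKM, with edgeR if counts for all genes were deposited. The table of all genes holds FPKM, so limma remained the test and the count tests on recovered reads are alternatives.

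Genes with at least 1 FPKM in at least 3 libraries were kept (13194 genes), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries and trended empirical Bayes variances. Log2 fold changes and standard errors (SE) are on this scale, which understates the change of genes with low FPKM. The contrasts were DATS against DMSO in each cell line, the difference of these responses (SK-BR-3 minus MCF-10A), and SK-BR-3 against MCF-10A in DMSO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "rose" or "fell" is used of called genes. With 3 libraries in each group, the p-values rest on the spread between preparations, pooled over the 4 groups of both cell lines. The p-values of 1 line therefore depend in part on the libraries of the other. This fit does not pair libraries by replicate number.

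The genes named follow a rule fixed in advance. For each DATS comparison they are the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap and whose higher group averages at least 5 FPKM. For the difference of the responses they are the 6 largest each way, with at least 5 FPKM in any group and the groups not overlapping in the cell line with the larger response. Up to 4 tested members of each gene list with the largest absolute change are added for each comparison, and 12 genes are named whatever their result (HMOX1, NQO1, CCND1, PTGS2, ERBB2, STAT3, JUN, LDHA, FOXQ1, TUBB, CDKN1A and DDIT3). A gene named for 1 comparison is also printed for others. Between the DMSO groups the rule takes that panel and the identity lists. A gene outside the rule is said to be chosen after its values were seen.

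In advance, 40 gene lists were fixed that cover stress responses, metabolism, the cell cycle, signalling, epithelial identity, and markers of fibroblasts, endothelium and leukocytes. Each was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, again with a correlation estimated for each list, and with fry. Called members were also counted with p-values adjusted over the list alone. Overlaps of called genes were tested with Fisher's exact test. Positions are from GENCODE 29 on GRCh38.

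The replicate numbers come from the labels, which do not say that a number marks a shared day. They were treated as pairing the samples because same-numbered libraries deviated together: the correlations of deviations from the group means were 0.21, 0.19 and 0.33 in MCF-10A and 0.39, 0.24 and 0.25 in SK-BR-3, all above the limit of 0.1 set in advance. Of the pairs with different numbers, MCF-10A DMSO 2 with DATS 1 also passed that limit (0.11). The others lay below it, the highest at 0.087 in SK-BR-3. The fit with the replicate number within each cell line as a block is given beside a result where it changes a call or moves a count by over 1.5 times.

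The alternatives tried were a pseudocount of 0.1, no filter or a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, each cell line alone, the replicate block, robust variances, an adjusted p under 0.01, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. After the data were examined, fits without a preparation that stood apart, fits with the trend of each library with GC content and gene length removed, and the replicate block with an estimated correlation for the gene lists were added.

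The gene tests (limma, edgeR, DESeq2 and limma with the block) and camera at the preset correlation were checked on simulated reads drawn from the real means and library sizes, with 100 genes changed at each fold. For MCF-10A limma recovered 41% of the 1.5-fold and 74% of the 2-fold changes with 13 false calls (13193 genes). For SK-BR-3 it recovered 26% and 75% with 6 false calls (13194 genes). For the difference of the responses the shares were 4% and 34% with 2 false calls (13194 genes), and between the DMSO groups 30% and 76% with 6 false calls (13054 genes). With the replicate block, simulated without any pairing, the shares were 18% and 59% in MCF-10A, 15% and 62% in SK-BR-3, and 0% and 0% for the difference of the responses. Of 39 random gene lists camera called 0 in each of the 3 DATS simulations. Genes were drawn independently of each other there, so this does not test calls of lists whose genes move together. The tests with an estimated correlation, fry and Fisher's exact test were not simulated.

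Genes whose reads are shared with near-identical copies or pseudogenes (ferritins, tubulins, keratins, metallothioneins, histones, AKR1C and HSPA1 genes, SPRR2 and PSG families, ribosomal proteins) are uncertain, since the handling of reads that map to several genes is not given in the sources used here. The same holds for genes that overlap another gene, such as KRT8 and KRT18.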

Results

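Diallyl trisulfide (DATS), an organosulfur compound of garlic, raised NQO1 and lowered E2F1 after 16 h at 20 µM in both breast cell lines studied. CXCL8 rose in MCF-10A and CDC20 rose in SK-BR-3. These calls hold whichever library is left out, while limma on the 6 MCF-10A libraries alone called 0 genes (lowest adjusted p = 0.0514). MCF-10A is a spontaneously immortalised, non-tumorigenic breast epithelial line, and SK-BR-3 is a breast cancer line with an amplified ERBB2 (HER2) gene. Each line was given DATS or its solvent DMSO in 3 independent preparations, which made 12 libraries. Values are FPKM from the authors, fragments scaled to gene length and sequencing depth, as mean ± SD of n = 3 libraries, and log2 fold changes ± SE come from limma on log2(FPKM + 1). Libraries held 15295046 to 18407213 reads in genes, and 13194 genes were tested.

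In MCF-10A cells CXCL8, which encodes the neutrophil attractant interleukin 8 (chromosome 4, 73740506 to 73743716, GRCh38), rose from 26.4 ± 15.2 to 119 ± 34.7 FPKM (log2 fold change 2.22 ± 0.32, adjusted p = 0.00585). CSF3, the granulocyte growth factor, rose from 27.5 ± 13 to 123 ± 48.5 FPKM (2.18 ± 0.35, adjusted p = 0.00889). CCL20, a chemokine for lymphocytes and dendritic cells, rose from 2.39 ± 0.386 to 21.2 ± 13.4 FPKM (2.44 ± 0.43, adjusted p = 0.0124). IL24, an IL-10 family cytokine, rose from 1.07 ± 0.944 to 9.69 ± 4.95 FPKM (2.35 ± 0.35, adjusted p = 0.00667), and LIF, an IL-6 family cytokine, rose from 2.90 ± 1.85 to 15.4 ± 5.24 FPKM (2.12 ± 0.32, adjusted p = 0.00702).

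Among the NF-kB and inflammatory genes, 21 of 28 genes were higher (25 higher when adjusted over the list alone, camera adjusted p = 9.98e-21, adjusted p = 0.193 with an estimated correlation). Their median log2 change was 1.32. BIRC3, an inhibitor of apoptosis induced by NF-kB, rose from 2.48 ± 0.320 to 10.3 ± 2.86 FPKM (1.66 ± 0.20, adjusted p = 0.00305), and the adhesion molecule ICAM1 rose from 2.75 ± 0.583 to 8.62 ± 2.84 FPKM (1.32 ± 0.21, adjusted p = 0.00913). PTGS2, the inducible cyclooxygenase, rose from 1.54 ± 0.150 to 3.81 ± 0.665 FPKM (0.91 ± 0.10, adjusted p = 0.00305). MCF-10A preparation 3 stood apart from the others. Its list median was 0.60, against 1.58 and 1.57 in preparations 1 and 2, and CXCL8 in DMSO was 43.9 FPKM there against 16.7 and 18.6 FPKM. With DATS the share of ribosomal RNA rose from 0.249% to 0.365% and from 0.243% to 0.386% in preparations 1 and 2. In preparation 3 it was 0.257% and 0.261%. The inflammatory rise was not tested against this share.

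**Figure D1:**
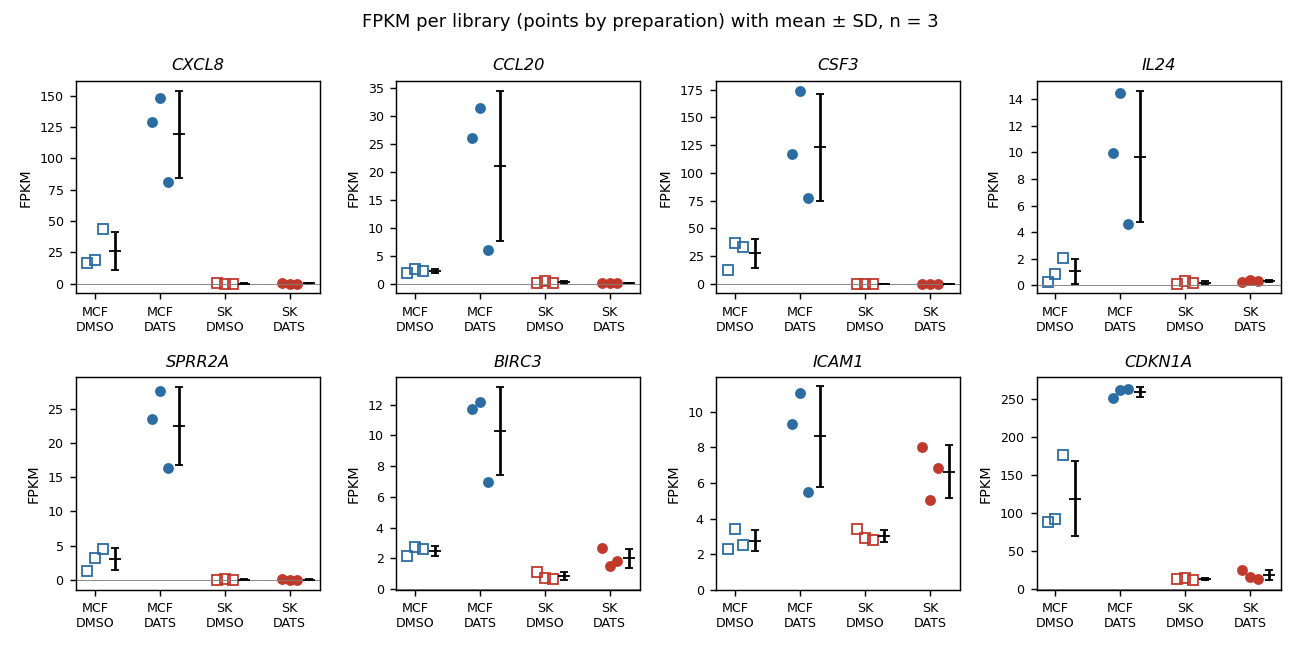
FPKM of 8 genes in each library (open squares DMSO, filled circles DATS, black marks the mean ± SD of 3 libraries) for MCF-10A and SK-BR-3. CXCL8 in MCF-10A rose from a mean of 26.4 to 119 FPKM, and stayed under 1 FPKM in SK-BR-3 with means of 0.178 and 0.301.

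SPRR2A, a cornified envelope protein (chromosome 1, 153056113 to 153057537), rose from 3.02 ± 1.58 to 22.5 ± 5.65 FPKM (2.6 ± 0.26, adjusted p = 0.00216), with reads that related SPRR2 copies could share. IL36G, an epidermal IL-1 family cytokine, rose from 2.84 ± 2.28 to 16.4 ± 7.63 FPKM (2.24 ± 0.38, adjusted p = 0.0113). C15orf48 rose from 3.53 ± 3.16 to 18.5 ± 3.74 FPKM (2.32 ± 0.39, adjusted p = 0.0103). PLAU, the urokinase plasminogen activator, rose from 59.4 ± 34.8 to 216 ± 19.3 FPKM (1.99 ± 0.35, adjusted p = 0.0124), and HBEGF, a ligand of the EGF receptor, rose from 8.11 ± 3.35 to 25.4 ± 2.51 FPKM (1.59 ± 0.21, adjusted p = 0.00451).

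Of the p53 targets, 7 of 28 genes were higher (13 higher when adjusted over the list alone), with 11 higher in the fit with the replicate block (camera adjusted p = 2.79e-06, adjusted p = 0.193 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339), rose from 119 ± 49.6 to 259.7 ± 6.51 FPKM (1.19 ± 0.25, adjusted p = 0.0234), and GDF15, a stress-induced cytokine, rose from 6.29 ± 0.642 to 24.2 ± 9.94 FPKM (1.70 ± 0.44, adjusted p = 0.0433). Leaving out 1 library ended the CDKN1A call for 5 of the 12 libraries and the GDF15 call for 6 (adjusted p up to 0.117 and 0.154). In preparation 3, which stood apart, the median of the p53 list was 0.13, against 0.45 and 0.52 in preparations 1 and 2. That preparation also had the lowest share of ribosomal RNA with DATS, and the p53 rise was not tested against it. Of the NRF2 targets, which answer oxidative and electrophilic stress, 10 of 31 genes were higher (14 higher when adjusted over the list alone, camera adjusted p = 1.15e-06, adjusted p = 0.148 with an estimated correlation). HMOX1, heme oxygenase 1 (chromosome 22, 35380361 to 35394214), rose from 2.42 ± 1.19 to 5.78 ± 0.463 FPKM (1.05 ± 0.25, adjusted p = 0.034), and NQO1, a quinone reductase, rose from 64.1 ± 0.0716 to 96.2 ± 7.46 FPKM (0.57 ± 0.07, adjusted p = 0.00318). The HMOX1 call was lost when any 1 of 6 libraries was left out (adjusted p up to 0.134). The ferritin light chain FTL, whose reads pseudogenes could share, rose from 561 ± 34.3 to 1277 ± 102 FPKM (1.19 ± 0.17, adjusted p = 0.0057).

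Of the interferon-stimulated genes, 10 of 27 genes were higher (14 higher when adjusted over the list alone, camera adjusted p = 3.11e-07, adjusted p = 0.271 with an estimated correlation). IFIT3 rose from 4.10 ± 0.614 to 7.66 ± 1.39 FPKM (0.76 ± 0.13, adjusted p = 0.0119). Of the autophagy and lysosome genes, 5 of 35 genes were higher (11 higher when adjusted over the list alone), with 14 higher in the fit with the replicate block (camera adjusted p = 4.5e-05, adjusted p = 0.367 with an estimated correlation). WIPI1, a protein of the early autophagosome, rose by 0.62 ± 0.10, adjusted p = 0.00889. Of the apoptosis regulators, 5 of 26 genes were higher (11 higher when adjusted over the list alone), with 8 higher in the fit with the replicate block (camera adjusted p = 0.00025, adjusted p = 0.271 with an estimated correlation). BIK, a pro-apoptotic BCL2 family member, rose (0.85 ± 0.17, adjusted p = 0.0177), as did the anti-apoptotic BCL2L1 (0.86 ± 0.22, adjusted p = 0.0428). The apoptosis list had a median of 0.07 in preparation 3, against 0.30 and 0.28 in preparations 1 and 2. Of the ER chaperones, 3 of 26 genes were higher (4 higher when adjusted over the list alone), with 9 higher in the fit with the replicate block (camera adjusted p = 0.00025, adjusted p = 0.367 with an estimated correlation). HSPA5 rose by 0.36 ± 0.09, adjusted p = 0.0482. Of the FOXO targets, 3 of 23 genes were higher (4 higher when adjusted over the list alone), with 9 higher in the fit with the replicate block (camera adjusted p = 0.00208, adjusted p = 0.367 with an estimated correlation). The FOXO call was lost without 1 library (adjusted p = 0.0544).

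Several lists of cell shape and signalling were also called higher in MCF-10A. Of the actin cytoskeleton genes, 3 of 23 genes were higher, with 12 higher in the fit with the replicate block (camera adjusted p = 0.000142, adjusted p = 0.457 with an estimated correlation). TAGLN, an actin-binding protein, rose from 14.7 ± 5.09 to 36.1 ± 6.42 FPKM (1.27 ± 0.24, adjusted p = 0.0148). Of the mesenchymal genes, 4 of 21 genes were higher and 1 lower (7 higher when adjusted over the list alone), with 8 higher and 1 lower in the fit with the replicate block (camera adjusted p = 0.00675, adjusted p = 0.409 with an estimated correlation). The repressor SNAI1 had a log2 change of 0.74 ± 0.16, adjusted p = 0.0235. Of the matrix and adhesion genes, 5 of 23 genes were higher and 1 lower (8 higher when adjusted over the list alone), with 10 higher and 2 lower in the fit with the replicate block (camera adjusted p = 0.00675, adjusted p = 0.416 with an estimated correlation). Of the ERBB family signalling genes, 3 of 23 genes were higher and 1 lower (8 higher when adjusted over the list alone), with 8 higher and 1 lower in the fit with the replicate block (camera adjusted p = 0.0177, adjusted p = 0.367 with an estimated correlation). The ligand TGFA had a log2 change of 0.86 ± 0.20, adjusted p = 0.0282. The ERBB family list had medians of 0.06, 0.18 and 0.22 in preparations 1, 2 and 3, and lost its call when either of 2 libraries was left out (adjusted p up to 0.129). Of the AP-1 and immediate early genes, 5 of 29 genes were higher (6 higher when adjusted over the list alone), with 10 higher and 2 lower in the fit with the replicate block (camera adjusted p = 0.029, adjusted p = 0.702 with an estimated correlation). MAFF had a log2 change of 1.07 ± 0.18, adjusted p = 0.0118. The AP-1 list was not called with the trends of GC content and gene length removed (adjusted p = 0.0534, and 0.0504 with the replicate block) or when either of 2 libraries was left out (adjusted p up to 0.0694). Of the hypoxia targets, 3 of 21 genes were higher (6 higher when adjusted over the list alone), with 8 higher in the fit with the replicate block (camera adjusted p = 0.00218, adjusted p = 0.367 with an estimated correlation). ANGPTL4, a regulator of lipoprotein lipase, had a log2 change of 2.10 ± 0.56, adjusted p = 0.0489. The hypoxia list had a median of 0.10 in preparation 3, against 0.25 and 0.42, and lost its call without 1 library (adjusted p = 0.0551).

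Luminal keratins and histones completed the called lists that were higher in MCF-10A. Of the luminal markers, 3 of 11 genes were higher (6 higher when adjusted over the list alone), with 6 higher in the fit with the replicate block (camera adjusted p = 0.00175, adjusted p = 0.367 with an estimated correlation). FOXA1, a luminal transcription factor, rose from 3.94 ± 0.935 to 6.95 ± 0.599 FPKM (0.70 ± 0.13, adjusted p = 0.0149), and KRT8 rose by 0.92 ± 0.15, adjusted p = 0.0103, with reads that keratin pseudogenes could share. Of the histone genes, 4 of 12 genes were higher (5 higher when adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.271 with an estimated correlation). HIST1H1C rose from 9.06 ± 4.71 to 21.7 ± 2.04 FPKM (1.27 ± 0.24, adjusted p = 0.0157), uncertain because histone copies are alike. The histone list was fixed as a measure of library quality, and its medians were 0.71, 0.97 and 0.33 in preparations 1, 2 and 3. The share of ribosomal RNA, mitochondrial included, moved with it. It was 0.249%, 0.243% and 0.257% of the reads with DMSO and 0.365%, 0.386% and 0.261% with DATS. The histone rise is thus not set apart from library quality. The inflammatory, p53, apoptosis and hypoxia lists were also lowest in preparation 3. So were the interferon, actin, mesenchymal, AP-1, FOXO, ER chaperone and luminal lists (luminal 0.42, 0.44 and 0.21 in preparations 1, 2 and 3). Among the called falls, those of DNA replication (−0.60, −0.59 and −0.34), DNA repair and ribosome biogenesis were smallest there. None of these lists is set apart from library quality either. The NRF2 list was not lowest in preparation 3 (0.22, 0.28 and 0.29 in preparations 1, 2 and 3), nor were the autophagy, matrix and ERBB family lists. The G2/M fall was largest there.

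Lists of cell cycle genes were called lower in MCF-10A cells. Of the DNA replication and G1/S genes, 24 of 43 genes were lower (37 lower when adjusted over the list alone), with 37 lower in the fit with the replicate block (camera adjusted p = 2.45e-29, adjusted p = 0.148 with an estimated correlation). Their median was -0.51. E2F1, a transcription factor of S-phase genes, fell from 13.7 ± 1.03 to 7.35 ± 1.42 FPKM (-0.82 ± 0.11, adjusted p = 0.00508), and MCM3, a subunit of the replicative helicase, fell from 51.8 ± 6.28 to 28.9 ± 3.55 FPKM (-0.82 ± 0.12, adjusted p = 0.00564). Of the G2/M and mitosis genes, 12 of 46 genes were lower (36 lower when adjusted over the list alone), with 34 lower in the fit with the replicate block (camera adjusted p = 3.09e-21, adjusted p = 0.271 with an estimated correlation). CCNB1, cyclin B1, fell from 103 ± 2.70 to 64.6 ± 12.4 FPKM (-0.68 ± 0.15, adjusted p = 0.028), and BIRC5, survivin, fell from 39 ± 1.58 to 23.1 ± 1.70 FPKM (-0.73 ± 0.14, adjusted p = 0.0148). Of the DNA repair genes, 11 of 34 genes were lower (18 lower when adjusted over the list alone, camera adjusted p = 1.66e-15, adjusted p = 0.161 with an estimated correlation). BRCA1 had a log2 change of -0.61 ± 0.13, adjusted p = 0.0221. Of the ribosome biogenesis genes, 4 of 34 genes were lower (9 lower when adjusted over the list alone), with 7 lower in the fit with the replicate block (camera adjusted p = 4.78e-10, adjusted p = 0.256 with an estimated correlation). Nucleolin, NCL, had a log2 change of -0.39 ± 0.08, adjusted p = 0.0211.

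The largest falls included E2F2 from 6.13 ± 1.45 to 2.30 ± 0.0362 FPKM (-1.09 ± 0.15, adjusted p = 0.00457), the atypical cadherin FAT2 (-0.95 ± 0.25, adjusted p = 0.0477), CDCA7 (-0.90 ± 0.13, adjusted p = 0.0057) and GAS1 (-0.89 ± 0.22, adjusted p = 0.0369). NOTCH3, a Notch receptor, fell from 5.33 ± 0.537 to 2.74 ± 0.205 FPKM (-0.76 ± 0.09, adjusted p = 0.00318). HSP90AA1, an inducible HSP90 chaperone, fell from 418 ± 19.4 to 288 ± 21.1 FPKM (-0.54 ± 0.09, adjusted p = 0.00913), while in the heat shock list as a whole 3 of 24 genes were lower and 1 higher, with 6 lower and 3 higher in the fit with the replicate block (camera adjusted p = 0.0783, adjusted p = 0.668 with an estimated correlation). The forkhead factor FOXQ1 fell (-0.48 ± 0.10, adjusted p = 0.0216). CCND1, cyclin D1, had 0.41 ± 0.18, adjusted p = 0.181, and it passed with the replicate block (adjusted p = 0.0143). STAT3 had 0.32 ± 0.11, adjusted p = 0.0944, and passed with the block at adjusted p = 0.0384. LDHA (0.06 ± 0.17, adjusted p = 0.881), JUN (-0.11 ± 0.39, adjusted p = 0.916), DDIT3 (0.31 ± 0.19, adjusted p = 0.355), TUBB (0.18 ± 0.15, adjusted p = 0.526) and ERBB2 (0.06 ± 0.07, adjusted p = 0.669) did not pass.

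In limma 550 genes were higher and 279 lower with DATS in MCF-10A, of which 72 and 8 changed at least 2-fold. Of the named genes called, 18 of 83 stayed called whichever library was left out. Of those printed above these were CXCL8, CSF3, IL24, LIF, BIRC3, PTGS2, SPRR2A, HBEGF, NQO1, FTL, E2F1, MCM3, E2F2, CDCA7 and NOTCH3, and all other calls printed were lost without some library. Ribosomal RNA, mitochondrial included, took 0.243% to 0.257% of the reads with DMSO and 0.261% to 0.386% with DATS. It was the only library measure of 8 that separated with treatment there. In 2276 genes all 3 DATS libraries lay above all 3 DMSO libraries and in 1609 below, 29.4% of the tested genes against 10% by chance. Fitted on the MCF-10A libraries alone, limma called 0 genes, with 3285 at an unadjusted p under 0.05, while on all 12 libraries edgeR called 510 higher and 276 lower and DESeq2 906 and 550. With the replicate block the counts were 1412 and 688. Quantile normalization gave 634 higher and 615 lower, 50.8% higher against 66.3%. Without DMSO library 3 the counts were 1296 and 649, and without DATS library 3 they were 322 and 126. They were 62 and 24 without DMSO library 1, 76 and 33 without DMSO library 2, 158 and 75 without DATS library 1, and 61 and 28 without DATS library 2.

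In SK-BR-3 cells TXNRD1, thioredoxin reductase 1, rose from 119 ± 20.2 to 297 ± 27.8 FPKM (1.32 ± 0.11, adjusted p = 0.000147). GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis, rose from 12.1 ± 0.800 to 28.6 ± 2.31 FPKM (1.18 ± 0.09, adjusted p = 6.76e-05). HMOX1 rose from 14.2 ± 2.70 to 42.1 ± 12.4 FPKM (1.48 ± 0.25, adjusted p = 0.00334) and NQO1 from 89.9 ± 3.95 to 141 ± 1.92 FPKM (0.64 ± 0.07, adjusted p = 0.000457). The ferritin chain FTH1, whose reads pseudogenes could share, rose from 166 ± 18.7 to 477 ± 101 FPKM (1.5 ± 0.15, adjusted p = 0.000279). Of the NRF2 targets, 17 of 31 genes were higher (20 higher when adjusted over the list alone, camera adjusted p = 2.9e-09, adjusted p = 0.0868 with an estimated correlation). Their median was 0.44.

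**Figure D2:**
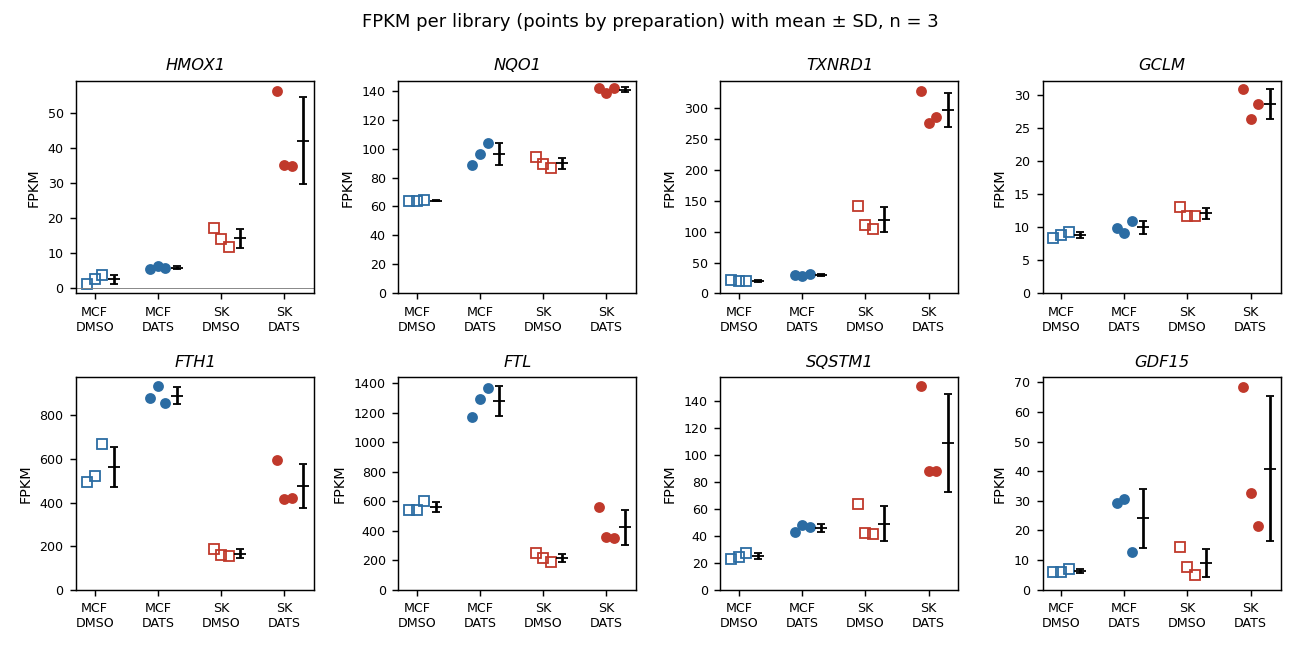
FPKM of 8 genes, NRF2 targets and GDF15 of the p53 list, in each library for MCF-10A and SK-BR-3. Open squares are DMSO, filled circles DATS, and black marks the mean ± SD of 3 libraries. TXNRD1 rose in SK-BR-3 from a mean of 119 to 297 FPKM, and GCLM from 12.1 to 28.6 FPKM.

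Lists of protein quality control were called higher in SK-BR-3. Of the heat shock genes, 12 of 24 genes were higher (13 higher when adjusted over the list alone, camera adjusted p = 0.00634, adjusted p = 0.575 with an estimated correlation). The small heat shock proteins HSPB1 (1066 ± 58.5 to 2336 ± 171 FPKM, 1.13 ± 0.19, adjusted p = 0.00334) and CRYAB (4.61 ± 2.16 to 15.6 ± 6.40 FPKM, 1.56 ± 0.38, adjusted p = 0.0165) rose, and so did the chaperone HSPB8 (2.89 ± 0.470 to 13.4 ± 0.468 FPKM, 1.89 ± 0.18, adjusted p = 0.000197). Of the proteasome genes, 10 of 33 genes were higher (11 higher when adjusted over the list alone), with 17 higher in the fit with the replicate block (camera adjusted p = 2.16e-05, adjusted p = 0.575 with an estimated correlation). PSMC6 had a log2 change of 0.46 ± 0.06, adjusted p = 0.0012. The proteasome list had medians of 0.43, 0.21 and 0.14 in the 3 preparations. Of the autophagy and lysosome genes, 14 of 35 genes were higher and 1 lower (21 higher when adjusted over the list alone, camera adjusted p = 4.29e-05, adjusted p = 0.575 with an estimated correlation). GABARAPL1 rose from 17.6 ± 4.13 to 32.4 ± 6.63 FPKM (0.85 ± 0.16, adjusted p = 0.00504) and the cargo receptor SQSTM1 from 49.1 ± 12.9 to 109 ± 36.4 FPKM (1.12 ± 0.21, adjusted p = 0.0054). Of the ferroptosis and iron genes, 9 of 20 genes were higher and 2 lower (11 higher when adjusted over the list alone, camera adjusted p = 0.00392, adjusted p = 0.134 with an estimated correlation). AIFM2, a ferroptosis suppressor, had a log2 change of 0.75 ± 0.13, adjusted p = 0.00358. Of the metallothioneins, 4 of 6 genes were higher (camera adjusted p = 0.0411, adjusted p = 0.575 with an estimated correlation). The list was not called with the replicate block (adjusted p = 0.0573) or when any 1 of 3 libraries was left out (adjusted p up to 0.129). It was called with the trends of GC content and gene length removed (adjusted p = 0.00433, and 0.00524 with the block as well). MT1G, uncertain among its near copies, rose by 1.34 ± 0.36, adjusted p = 0.026.

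CDC20, an activator of the anaphase-promoting complex (chromosome 1, 43358955 to 43363203), rose in SK-BR-3 from 93.4 ± 8.65 to 205 ± 12.6 FPKM (1.13 ± 0.13, adjusted p = 0.000477). CCNB1 (chromosome 5, 69167010 to 69178245) rose from 53.9 ± 9.29 to 98.7 ± 10.0 FPKM (0.87 ± 0.15, adjusted p = 0.00414), and the mitotic kinase AURKA from 88.2 ± 9.11 to 182 ± 20.4 FPKM (1.04 ± 0.13, adjusted p = 0.00074). Of the G2/M and mitosis genes, 27 of 46 genes were higher (32 higher when adjusted over the list alone, camera adjusted p = 4.61e-10, adjusted p = 0.575 with an estimated correlation). Their median was 0.53. Of the DNA replication and G1/S genes, 10 of 43 genes were lower (16 lower when adjusted over the list alone), with 20 lower and 1 higher in the fit with the replicate block (camera adjusted p = 1.26e-07, adjusted p = 0.575 with an estimated correlation). E2F1 fell from 26.0 ± 2.16 to 14.9 ± 0.931 FPKM (-0.77 ± 0.11, adjusted p = 0.00185). Of the DNA repair genes, 2 of 34 genes were lower (1 lower when adjusted over the list alone), with 4 lower in the fit with the replicate block (camera adjusted p = 0.0119, adjusted p = 0.575 with an estimated correlation). LIG1, DNA ligase 1, a member of the replication list and not of the repair list, had a log2 change of -0.63 ± 0.11, adjusted p = 0.00494. The repair list had medians of −0.17, −0.12 and −0.02, and lost its call without 1 library (adjusted p = 0.0909).

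Basal and mesenchymal lists were called higher in SK-BR-3. Of the basal markers, 7 of 15 genes were higher (8 higher when adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.456 with an estimated correlation). KRT17 rose from 8.09 ± 2.23 to 26.5 ± 6.97 FPKM (1.60 ± 0.22, adjusted p = 0.0014) and caveolin, CAV1, from 12.9 ± 0.961 to 23.5 ± 4.14 FPKM (0.81 ± 0.11, adjusted p = 0.00109). Of the mesenchymal genes, 8 of 21 genes were higher (camera adjusted p = 0.00937, adjusted p = 0.575 with an estimated correlation). The mesenchymal list had medians of 0.07, 0.15 and 0.58 in preparations 1, 2 and 3. The hyaluronan receptor CD44, from the list of stem cell and Notch genes, rose from 1.08 ± 0.330 to 3.87 ± 0.566 FPKM (1.24 ± 0.12, adjusted p = 0.000215). Of the matrix and adhesion genes, 5 of 23 genes were higher (6 higher when adjusted over the list alone), with 10 higher in the fit with the replicate block (camera adjusted p = 0.0185, adjusted p = 0.575 with an estimated correlation). TGFBI, a member of the mesenchymal list, had a log2 change of 1.45 ± 0.20, adjusted p = 0.00141. Of the actin cytoskeleton genes, 8 of 23 genes were higher (10 higher when adjusted over the list alone), with 15 higher in the fit with the replicate block (camera adjusted p = 0.00106, adjusted p = 0.575 with an estimated correlation). Of the hypoxia targets, 5 of 21 genes were higher, with 9 higher and 1 lower in the fit with the replicate block (camera adjusted p = 0.0351, adjusted p = 0.575 with an estimated correlation). ERO1A, an oxidase of the ER, had a log2 change of 1.18 ± 0.10, adjusted p = 0.000147. The hypoxia list was not called with the trends of GC content and gene length removed (adjusted p = 0.0915, and 0.0872 with the replicate block) or when any 1 of 3 libraries was left out (adjusted p up to 0.11).

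The largest rises in SK-BR-3 included CCL22, a chemokine (chromosome 16, 57358772 to 57366190), from 2.23 ± 0.672 to 14.2 ± 3.32 FPKM (2.24 ± 0.16, adjusted p = 5.96e-05). EEF1A2, a translation elongation factor, rose from 21.8 ± 2.12 to 88.2 ± 17.3 FPKM (1.95 ± 0.13, adjusted p = 5.3e-05), GDF15 from 8.98 ± 4.74 to 40.9 ± 24.5 FPKM (2.01 ± 0.44, adjusted p = 0.011) and KRT16 from 2.55 ± 0.397 to 11.8 ± 3.40 FPKM (1.82 ± 0.24, adjusted p = 0.00105). KPNA7 rose by 1.90 ± 0.19, adjusted p = 0.000276. PSG4 rose by 1.79 ± 0.32, adjusted p = 0.00463, uncertain among its near copies, and CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, by 1.66 ± 0.48, adjusted p = 0.0351. In the NF-kB and inflammatory list 4 of 28 genes were higher (1 higher when adjusted over the list alone, camera adjusted p = 0.185, adjusted p = 0.838 with an estimated correlation). ICAM1 rose from 3.05 ± 0.338 to 6.63 ± 1.48 FPKM (0.90 ± 0.21, adjusted p = 0.0155) and BIRC3 rose (0.71 ± 0.20, adjusted p = 0.0293).

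In SK-BR-3 SELENBP1, a methanethiol oxidase, fell from 73.3 ± 10.6 to 26.8 ± 7.98 FPKM (-1.45 ± 0.26, adjusted p = 0.00474), and the growth factor TGFB3 from 18 ± 4.82 to 5.98 ± 2.42 FPKM (-1.48 ± 0.25, adjusted p = 0.00312). SPDEF, a luminal transcription factor, fell from 87.8 ± 26.0 to 38.7 ± 12.9 FPKM (-1.17 ± 0.25, adjusted p = 0.0102), ID2 from 68.8 ± 24.8 to 28.2 ± 7.13 FPKM (-1.23 ± 0.22, adjusted p = 0.0046) and LRRC26 from 38.6 ± 7.28 to 15.1 ± 1.99 FPKM (-1.29 ± 0.12, adjusted p = 0.000197). CRACR2B (-1.56 ± 0.33, adjusted p = 0.0106), SERHL2 (-1.32 ± 0.24, adjusted p = 0.00439) and RAB26 (-1.22 ± 0.29, adjusted p = 0.0164) also fell. Of the hydrogen sulfide genes, 4 of 11 genes were lower and 1 higher (camera adjusted p = 0.0425, adjusted p = 0.575 with an estimated correlation). That list was not called with the trends of GC content and gene length removed (adjusted p = 0.246, and 0.291 with the replicate block) or when any 1 of 4 libraries was left out (adjusted p up to 0.174). Sulfite oxidase, SUOX, had a log2 change of -0.61 ± 0.10, adjusted p = 0.00358. Of the nuclear-encoded oxidative phosphorylation genes, 8 of 41 genes were lower (16 lower when adjusted over the list alone), with 13 lower in the fit with the replicate block (camera adjusted p = 1.26e-07, adjusted p = 0.575 with an estimated correlation). NDUFV1, a complex I subunit, fell from 66.9 ± 7.36 to 42.2 ± 4.33 FPKM (-0.65 ± 0.10, adjusted p = 0.00235). The oxidative phosphorylation list had medians of −0.02, −0.31 and −0.37 in the 3 preparations. Over all genes called in SK-BR-3, those lower had a median GC content of 57.0% and those higher 44.7%.

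ERBB2 itself (chromosome 17, 39687914 to 39730426) fell from 493 ± 23.6 to 389.6 ± 13.5 FPKM in SK-BR-3 (-0.34 ± 0.07, adjusted p = 0.00673). TUBB, a beta tubulin with near copies, fell from 445 ± 80.9 to 231 ± 30.8 FPKM (-0.94 ± 0.15, adjusted p = 0.00304), and in the tubulin list 2 of 13 genes were lower, with 5 lower and 2 higher in the fit with the replicate block (camera adjusted p = 0.0973, adjusted p = 0.575 with an estimated correlation). STAT3 rose by 0.46 ± 0.11, adjusted p = 0.0145. CCND1 had 0.26 ± 0.18, adjusted p = 0.342 and passed with the replicate block (adjusted p = 0.0359). CDKN1A (0.40 ± 0.25, adjusted p = 0.301), JUN (-0.37 ± 0.39, adjusted p = 0.575), LDHA (0.03 ± 0.17, adjusted p = 0.954), FOXQ1 (0.01 ± 0.10, adjusted p = 0.963) and DDIT3 (0.01 ± 0.19, adjusted p = 0.998) did not pass. PTGS2 averaged 0 FPKM in DMSO (0.04 ± 0.10, adjusted p = 0.855).

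In limma 1485 genes were higher and 906 lower with DATS in SK-BR-3, of which 95 and 53 changed at least 2-fold. Whichever library was left out, 67 of 114 named genes stayed called, and of those printed above only CRYAB, MT1G, CYP1A1, ICAM1, BIRC3, RAB26 and STAT3 lost their call without some library. Library measures also moved with DATS there. Reads in genes were 15295046 to 17619720 with DMSO and 17950949 to 18182059 with DATS, and the ratio of effective library size to that total was 0.930 to 0.982 and 0.886 to 0.919. Ribosomal RNA, mitochondrial included, took 0.344% to 0.410% and 0.427% to 0.557% of the reads. Genes neither protein-coding nor mitochondrial took 1.46% to 1.62% and 1.08% to 1.26%. In 2786 genes all 3 DATS libraries lay above all 3 DMSO libraries and in 1638 below, 33.5% of the tested genes against 10% by chance. With the replicate block the counts were 2257 and 1364, and on the SK-BR-3 libraries alone 630 and 287. The share of higher genes was 62.1% in limma, 52.9% with median-of-ratios scaling (1208 higher, 1074 lower) and 50.8% in edgeR (1145 and 1111). It was 53.5% with quantile normalization and 59.4% in DESeq2 (1724 and 1176). Without DMSO library 2 the counts were 875 and 508, without DMSO library 3 they were 792 and 461, and without DATS library 3 they were 807 and 481.

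For the difference between the cell lines, higher and lower refer to the response of SK-BR-3 minus that of MCF-10A. CDC20 fell in MCF-10A from 136 ± 4.23 to 86.6 ± 16.4 FPKM and rose in SK-BR-3 from 93.4 ± 8.65 to 205 ± 12.6 FPKM, a difference of responses of 1.79 ± 0.18, adjusted p = 0.00182. Its fall in MCF-10A (-0.66 ± 0.13, adjusted p = 0.0161) was not called when any 1 of 3 libraries was left out (adjusted p up to 0.0788). CCNB1 differed by 1.55 ± 0.22, adjusted p = 0.00627, and CDKN3, a phosphatase of cyclin-dependent kinases, by 1.54 ± 0.22, adjusted p = 0.00647. Of the G2/M and mitosis genes, 33 of 46 genes were higher (38 higher when adjusted over the list alone, camera adjusted p = 5.8e-30, adjusted p = 0.356 with an estimated correlation). Their median was 1.00. The list median lay below 0 in the 3 MCF-10A preparations (−0.41, −0.39 and −0.56) and above 0 in the 3 SK-BR-3 preparations (0.50, 0.48 and 0.61). Of the DNA replication and G1/S genes, 3 of 43 genes were higher (5 higher when adjusted over the list alone), with 8 higher in the fit with the replicate block (camera adjusted p = 2.64e-05, adjusted p = 0.486 with an estimated correlation). Of the DNA repair genes, 1 of 34 genes was higher (0 higher when adjusted over the list alone), with 2 higher in the fit with the replicate block (camera adjusted p = 0.00036, adjusted p = 0.451 with an estimated correlation).

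**Figure D3:**
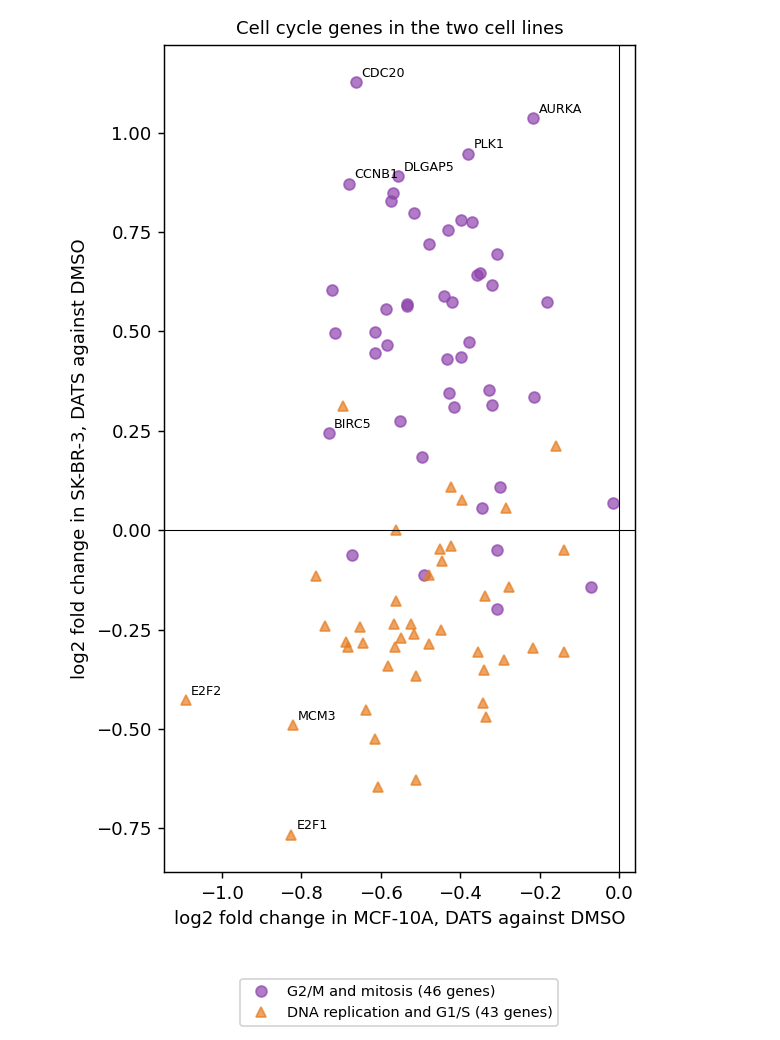
Log2 fold change with DATS in MCF-10A (horizontal) and SK-BR-3 (vertical) of 46 G2/M and mitosis genes (circles) and 43 DNA replication and G1/S genes (triangles). CDC20 lies at −0.66 and 1.13, and E2F1 at −0.82 and −0.77.

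SPRR2A differed by -2.60 ± 0.36, adjusted p = 0.00627, CCL20 by -2.54 ± 0.60, adjusted p = 0.0417, LIF by -2.34 ± 0.46, adjusted p = 0.0224 and CSF3 by -2.19 ± 0.49, adjusted p = 0.0344. IL24 differed by -2.21 ± 0.50, adjusted p = 0.035 and IL36G by -2.17 ± 0.54, adjusted p = 0.047, and neither passed with the replicate block (adjusted p = 0.0518 and 0.0728). CXCL8 differed by -2.10 ± 0.45, adjusted p = 0.0306. Apart from LIF, these genes lay under 1 FPKM in every SK-BR-3 library, where log2(FPKM + 1) leaves little room to see a response. Of the NF-kB and inflammatory genes, 9 of 28 genes were lower (19 lower when adjusted over the list alone, camera adjusted p = 2.21e-11, adjusted p = 0.356 with an estimated correlation). Their median was -0.97. Of the interferon-stimulated genes, 1 of 27 genes was lower (2 lower when adjusted over the list alone), with 3 lower in the fit with the replicate block (camera adjusted p = 0.0118, adjusted p = 0.555 with an estimated correlation). The interferon call was lost when any 1 of 3 libraries was left out (adjusted p up to 0.146). Of the AP-1 genes, 0 of 29 genes were lower, with 6 lower in the fit with the replicate block (camera adjusted p = 0.0147, adjusted p = 0.709 with an estimated correlation). The AP-1 list was not called with the trends of GC content and gene length removed (adjusted p = 0.0659), though it was called when the replicate block was added to that fit (adjusted p = 0.0145). It was not called when any 1 of 3 libraries was left out (adjusted p up to 0.221). PTGS2 differed by -0.87 ± 0.15, adjusted p = 0.012. SK-BR-3 DMSO libraries had 0 FPKM of PTGS2, so this value depends on the pseudocount, and count tests gave the opposite sign.

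GCLM differed by 1.02 ± 0.12, adjusted p = 0.00371, TXNRD1 by 0.79 ± 0.16, adjusted p = 0.0266 and the glutathione peroxidase GPX2 by 1.55 ± 0.33, adjusted p = 0.0294. Of the NRF2 targets, 5 of 31 genes were higher (10 higher when adjusted over the list alone), with 10 higher in the fit with the replicate block (camera adjusted p = 0.00771, adjusted p = 0.356 with an estimated correlation). Of the heat shock genes, 4 of 24 genes were higher (12 higher when adjusted over the list alone), with 10 higher and 1 lower in the fit with the replicate block (camera adjusted p = 0.000145, adjusted p = 0.356 with an estimated correlation). HSP90AA1 differed by 0.88 ± 0.12, adjusted p = 0.00612. Of the proteasome genes, 2 of 33 genes were higher, with 4 higher in the fit with the replicate block (camera adjusted p = 0.000392, adjusted p = 0.589 with an estimated correlation). The proteasome call was lost without 1 library (adjusted p = 0.052). Of the fatty acid synthesis genes, 2 of 20 genes were higher (3 higher when adjusted over the list alone, camera adjusted p = 0.0427, adjusted p = 0.589 with an estimated correlation). That list was not called with the replicate block (adjusted p = 0.0649) or with the trends of GC content and gene length removed (adjusted p = 0.0821, and 0.111 with the block), nor when any 1 of 6 libraries was left out (adjusted p up to 0.144). HMOX1 (0.44 ± 0.35, adjusted p = 0.518) and NQO1 (0.07 ± 0.10, adjusted p = 0.753) did not differ by the test. Of the p53 targets, 1 of 28 genes was lower (0 lower when adjusted over the list alone), with 5 lower in the fit with the replicate block (camera adjusted p = 0.00183, adjusted p = 0.356 with an estimated correlation). CDKN1A had a difference of -0.79 ± 0.36, adjusted p = 0.235, which did not pass.

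Of the basal markers, 5 of 15 genes were higher (camera adjusted p = 0.000383, adjusted p = 0.356 with an estimated correlation). KRT16 differed by 2.18 ± 0.34, adjusted p = 0.00806. Of the luminal markers, 3 of 11 genes were lower (5 lower when adjusted over the list alone), with 5 lower in the fit with the replicate block (camera adjusted p = 0.000683, adjusted p = 0.41 with an estimated correlation). MUC1 differed by -1.54 ± 0.31, adjusted p = 0.0233. Of the ERBB2 amplicon genes, 1 of 11 genes was lower (5 lower when adjusted over the list alone), with 3 lower in the fit with the replicate block (camera adjusted p = 0.0197, adjusted p = 0.356 with an estimated correlation). The amplicon list was not called with the trends of GC content and gene length removed (adjusted p = 0.0735, and 0.0574 with the replicate block). ERBB2 differed by -0.39 ± 0.09, adjusted p = 0.0406. Of the tubulins, 1 of 13 genes was lower (5 lower when adjusted over the list alone), with 5 lower in the fit with the replicate block (camera adjusted p = 0.00208, adjusted p = 0.356 with an estimated correlation). TUBB differed by -1.12 ± 0.22, adjusted p = 0.0224. CCL22 differed by 2.17 ± 0.22, adjusted p = 0.00182. MCF-10A DMSO libraries had 0 FPKM of CCL22, so this value depends on the pseudocount, and count tests gave the opposite sign.

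Metabolic and nuclear lists made up the rest. Of the hydrogen sulfide genes, 3 of 11 genes were lower (camera adjusted p = 0.00231, adjusted p = 0.41 with an estimated correlation). SELENBP1 differed by -1.52 ± 0.37, adjusted p = 0.0452. Of the oxidative phosphorylation genes, 0 of 41 genes were lower, with 1 lower in the fit with the replicate block (camera adjusted p = 0.000392, adjusted p = 0.7 with an estimated correlation). Of the ribosome biogenesis genes, 1 of 34 genes was higher (camera adjusted p = 0.00371, adjusted p = 0.555 with an estimated correlation). Of the histone genes, 1 of 12 genes was lower (4 lower when adjusted over the list alone), with 3 lower in the fit with the replicate block (camera adjusted p = 0.000383, adjusted p = 0.356 with an estimated correlation). That list was fixed as a measure of library quality. HIST2H2BE, uncertain among its near copies, differed by -1.13 ± 0.24, adjusted p = 0.03.

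**Figure D4:**
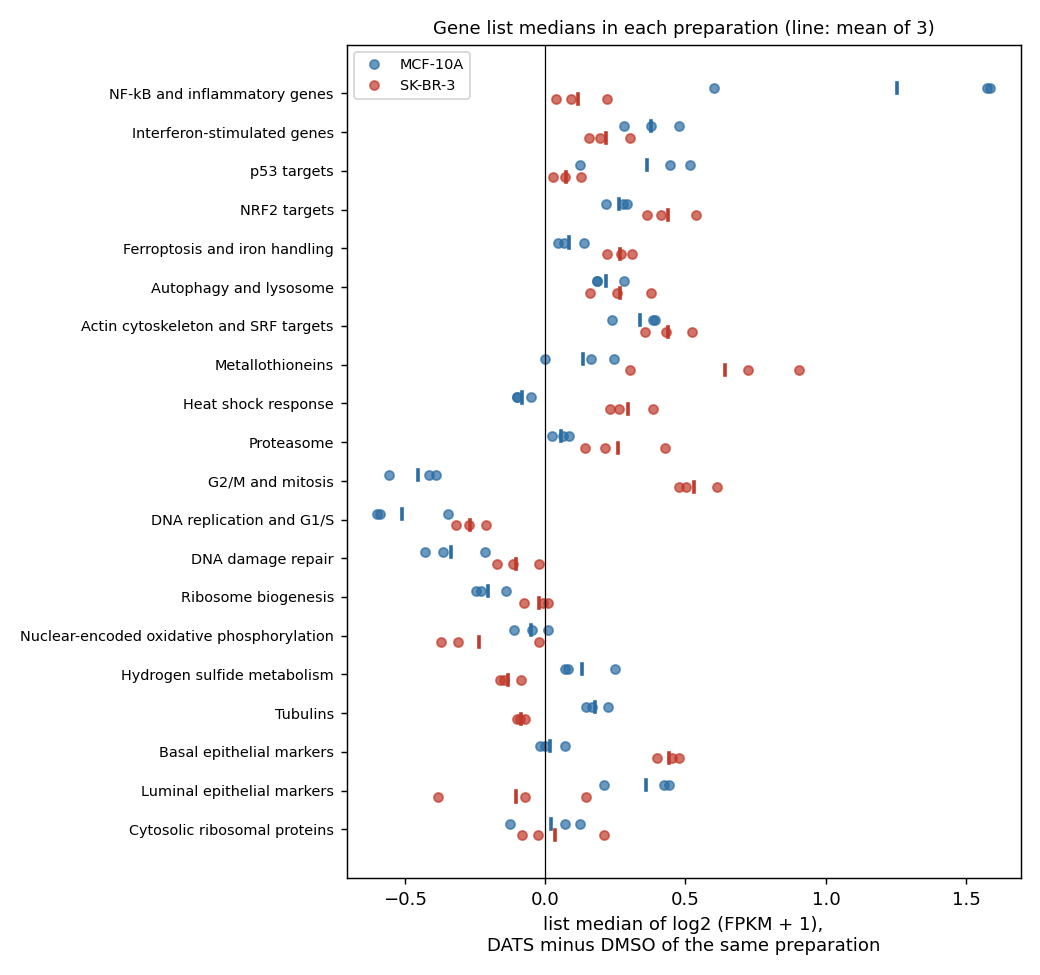
Median over each of 20 gene lists of the log2(FPKM + 1) difference between the DATS and DMSO libraries of a preparation (points, MCF-10A blue, SK-BR-3 red, short line the mean of 3 preparations). NF-kB and inflammatory genes lie at 1.58, 1.57 and 0.60 in MCF-10A, and G2/M and mitosis genes at 0.50, 0.48 and 0.61 in SK-BR-3.

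The response differed between the lines in 566 genes, 327 higher and 239 lower in SK-BR-3 minus MCF-10A, and with the replicate block in 698 and 598. The share of higher genes was 57.8% in limma, 53.9% with the block, 51.0% with median-of-ratios scaling (270 higher, 259 lower), 52.8% in edgeR (245 and 219) and 47.8% without MCF-10A preparation 3 (425 and 465). It was 56.3% in DESeq2, 58.7% with quantile normalization and 65.3% with a pseudocount of 0.1. The majority thus depends on the scaling, the test and the libraries. Of the named genes called, 19 of 58 stayed called whichever library was left out. Of those printed above these were CDC20, CCNB1, CDKN3, SPRR2A, GCLM, HSP90AA1, KRT16, CCL22 and PTGS2. Of the libraries left out in turn, those of MCF-10A gave 92 and 64 (DMSO 1), 88 and 48 (DMSO 2), 519 and 516 (DMSO 3), 123 and 63 (DATS 1), and 94 and 50 (DATS 2). Those of SK-BR-3 gave 129 and 75 (DMSO 2), 118 and 60 (DMSO 3), and 126 and 80 (DATS 3).

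Of the genes called higher, 145 were shared against 61.9 expected of independent calls (Fisher's exact test, one-sided, p = 6.26e-24), and of those called lower 58 against 19.2 (p = 1.41e-14). Both sets of calls rest on 1 variance per gene pooled over the lines, and genes that move together were counted as independent. The p-values of Fisher's exact test in this paragraph can therefore overstate the evidence. With the replicate block 535 and 182 were shared. Leaving out 1 library gave 14 to 367 and 6 to 101 shared genes, and fits on each line alone gave 0 and 0. NQO1 rose in both lines and E2F1 fell in both whichever library was left out. Another 11 genes were higher in MCF-10A and lower in SK-BR-3 (37.8 expected), and 29 the reverse (31.4 expected). Among genes changed at least 2-fold, 6 were shared higher against 0.518 expected (Fisher's exact test, one-sided, p = 1.27e-05). Over 13194 genes the log2 fold changes of the lines had a Pearson correlation of 0.296 and a Spearman correlation of 0.304.

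Without DATS the lines differed in identity. KRT14, a basal keratin, averaged 1541 FPKM in MCF-10A and 0.111 FPKM in SK-BR-3 (-10.44 ± 0.11, adjusted p = 2.33e-14), and SPDEF averaged 0.0481 and 87.8 FPKM (6.36 ± 0.25, adjusted p = 5.91e-10). ERBB2 was higher in SK-BR-3 at 493 FPKM than in MCF-10A at 8.26 FPKM (5.74 ± 0.07, adjusted p = 2.93e-14), and its amplicon neighbour GRB7 had 4.82 ± 0.14, adjusted p = 3.82e-11. Of the basal markers, 15 of 15 genes were lower (camera adjusted p = 2.55e-09, adjusted p = 0.0507 with an estimated correlation). Of the ERBB2 amplicon genes, 11 of 11 genes were higher (camera adjusted p = 1e-07, adjusted p = 0.0507 with an estimated correlation). Of the luminal markers, 8 of 11 genes were higher and 1 lower (camera adjusted p = 0.00253, adjusted p = 0.826 with an estimated correlation).

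Of the panel, HMOX1 (2.20 ± 0.25, adjusted p = 7.82e-06), STAT3 (1.57 ± 0.11, adjusted p = 8.04e-08), DDIT3 (0.89 ± 0.19, adjusted p = 0.00106), JUN (0.96 ± 0.39, adjusted p = 0.0447) and NQO1 (0.48 ± 0.07, adjusted p = 7.97e-05) were higher in SK-BR-3. CDKN1A (-2.99 ± 0.25, adjusted p = 5.84e-07), FOXQ1 (-2.32 ± 0.10, adjusted p = 1.22e-09), PTGS2 (-1.34 ± 0.10, adjusted p = 2.71e-07) and LDHA (-0.59 ± 0.17, adjusted p = 0.0071) were lower. CCND1 (0.41 ± 0.18, adjusted p = 0.0541) and TUBB (0.09 ± 0.15, adjusted p = 0.619) did not pass. In limma 4829 genes were higher and 4686 lower in SK-BR-3.

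The authors' deposited table for MCF-10A lists 3477 genes at an unadjusted p under 0.05, of which 1546 have an adjusted p under 0.05 and 1931 (55.5%) do not. Of the 1546 genes, 1462 were tested here, all with the same sign, and 734 (50.2%) were called, or 83.1% with the replicate block. The authors' deposited table for SK-BR-3 lists 4065 genes, of which 2119 have an adjusted p under 0.05 and 1946 (47.9%) do not. Of the 2119 genes, 1980 were tested, all with the same sign, and 1713 (86.5%) were called. Both calculations used the same libraries.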

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

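All tests below had a written prediction before they were run, except the comparison of the G2/M list with the replication list in SK-BR-3, which was chosen after its result had been seen. Before the scaling and handling predictions were written, the counts of higher and lower genes in edgeR and the medians of the AP-1 list were already known. A spread given below is a standard error of a median over genes, which are treated as independent. It leaves out the variation between preparations, so it can overstate the certainty.

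Mitotic genes drew attention because their response differed between the cell lines, with a median difference of 1.00 (adjusted p = 0.356 with an estimated correlation). Median-of-ratios scaling left it at 0.97 (spread 0.06), and the replicate block with the trends of GC content and gene length removed left it at 0.91 (spread 0.06), so neither explained it. The direction of the cell line appeared in 6 of 6 preparations. In SK-BR-3 the G2/M list changed by 0.80 (spread 0.07) more than the replication list, as a larger share of cells in G2/M could produce. Transcripts alone leave that explanation open, and a count of cells by DNA content would test it.

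Inflammatory genes differed in their response by a list median of −0.97 (adjusted p = 0.356 with an estimated correlation). Leukocytes or fibroblasts in the cultures did not account for the rise in MCF-10A, since 0 of 6 of their markers rose 2-fold to 1 FPKM or more. For handling at harvest, the median change of 6 immediate early genes was −0.57 (spread 0.25), below the limit set in the prediction. None of the 6 was called in limma (adjusted p from 0.349 to 0.944). With the replicate block EGR1 and FOS were called lower (adjusted p = 0.00687 and 0.0217). The AP-1 and immediate early list that holds them was called higher (median 0.24, camera adjusted p = 0.029, 0.702 with an estimated correlation). These measures point in different directions, so handling stays open. Library quality was not tested as a cause. The median of the inflammatory list was above 0 in 3 of 3 MCF-10A preparations.

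Genes lower with DATS in SK-BR-3 were rich in GC. With the replicate block and the trends of GC content and gene length removed, 83.6% of them stayed called, against 98.0% with the block alone and 66.9% with the trends removed without the block. The trends did not explain most of these calls, though the fit without the block leaves a part of them open. Median-of-ratios scaling kept 99.9%, but it moved the folds of SK-BR-3 down and raised the lower calls from 906 to 1074. It was thus unable to end these calls, and scaling remains open.

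Regrouped libraries were compared with the real groups. In MCF-10A 1 of 10 splits, the real one, reached 829 genes, and the highest other split gave 1 gene. In SK-BR-3 1 of 10 splits reached 2391 genes and the highest other gave 2, and between the DMSO groups 1 of 10 splits reached 9515 genes and the highest other gave 0. With 10 splits the smallest share possible is 0.1, too large to tell. Every other split there also mixes DATS with DMSO libraries, or the cell lines, within a group. The real differences then widen the spread within groups, which by itself lowers the counts of those splits. For the difference of the responses 2 of 100 splits reached 566 genes, and the highest other gave 2831, a split that exchanged DATS and DMSO in 1 cell line and so added the responses.

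Other lists stood out because their responses differed between the cell lines by camera at the preset correlation. All list calls for the difference were lost with an estimated correlation (adjusted p from 0.356 to 0.709), and those of AP-1, fatty acid synthesis and the ERBB2 amplicon with the trends of GC content and gene length removed (adjusted p = 0.0659, 0.0821 and 0.0735). Leaving out 1 library ended the calls of AP-1, interferon, fatty acid and proteasome lists (adjusted p up to 0.221, 0.146, 0.144 and 0.052), and the block ended that of fatty acid synthesis (0.0649). The histone and AP-1 lists were fixed as measures of library quality and handling. The median difference was 0.22 for NRF2 targets, 0.37 for heat shock genes, 0.20 for proteasome genes, 0.15 for fatty acid synthesis genes and 0.27 for basal markers. It was 0.28 for DNA replication genes, 0.21 for DNA repair genes and 0.21 for ribosome biogenesis genes. It was −0.36 for hydrogen sulfide genes, −0.26 for p53 targets, −0.65 for histones, −0.42 for tubulins and −0.25 for AP-1 genes. It was −0.24 for interferon-stimulated genes, −0.21 for oxidative phosphorylation genes, −0.41 for luminal markers and −0.29 for the ERBB2 amplicon.

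Single genes stood out for the same reason in limma. The response was higher in SK-BR-3 for KRT16 (2.18), CDC20 (1.79), CCNB1 (1.55), GPX2 (1.55) and CDKN3 (1.54). It was lower for SPRR2A (−2.60), CCL20 (−2.54), LIF (−2.34), CSF3 (−2.19), TUBB (−1.12) and ERBB2 (−0.39). IL24 (−2.21) and IL36G (−2.17) were called lower, but not with the replicate block (adjusted p = 0.0518 and 0.0728). Leaving out some 1 library ended the calls of GPX2, CCL20, LIF, CSF3, TUBB, ERBB2, IL24 and IL36G, and none of the others named here. For CCL22 (2.17) and PTGS2 (−0.87) the direction stays open, since edgeR and DESeq2 gave −1.71 and −1.14 for CCL22 and 2.99 and 2.31 for PTGS2.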

How the results depend on the processing

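The counts depended on the fit more than the directions did, and the cause was not tested. With the replicate block the counts of higher and lower genes were 1412 and 688 in MCF-10A, 2257 and 1364 in SK-BR-3, and 698 and 598 for the difference. The shared genes were 535 and 182, and 83.1% of the authors' MCF-10A genes were called. The block kept 822 of 829, 2353 of 2391 and 548 of 566 calls, and of all named genes it ended 0, 0 and 2 calls and added 43, 19 and 43. Of the lists it ended those of metallothioneins and fatty acid synthesis and added tubulins in MCF-10A (adjusted p = 0.0236), cholesterol synthesis in SK-BR-3 (0.0356) and ferroptosis for the difference (0.0486), whose adjusted p with an estimated correlation, without the block, was 0.539, 0.721 and 0.356. It changed no other call of a list. Among the gene values printed it changed the calls of IL24 and IL36G for the difference and of CCND1 in both lines. In MCF-10A it changed those of STAT3, LAMB3, EGR1 and FOS, and no other printed call changed. Calls added for named genes in comparisons whose values are not printed are within the 43, 19 and 43. Without a filter the counts were 285 and 133 in MCF-10A and 152 and 98 for the difference, 44 and 17 were shared, and the authors' share was 20.7%. On each line alone they were 0 and 0 in MCF-10A and 630 and 287 in SK-BR-3, 0 and 0 were shared, and the authors' shares were 0% and 41.9%. At an adjusted p under 0.01 they were 66 and 29, 512 and 242, and 49 and 20, with 9 and 3 shared and authors' shares of 6.16% and 36.7%. DESeq2 gave 906 and 550 in MCF-10A and 616 and 478 for the difference, 313 and 136 shared, and an authors' share of 80.4%. Quantile normalization gave 615 lower in MCF-10A and 125 shared lower, a pseudocount of 0.1 gave 140 lower for the difference, and a filter at 5 FPKM gave 2854 lower between the DMSO groups. At 2-fold 6 and 0 genes were shared.

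Alternatives added after the data were seen were these. Without MCF-10A preparation 3 937 genes were higher in MCF-10A, 425 higher and 465 lower for the difference and 272 shared higher. Without SK-BR-3 preparation 1 472 were lower in MCF-10A. With the trends of GC content and gene length removed 437 were lower in MCF-10A and 95 shared lower. With the block as well the counts were 1705 and 932, 2246 and 1479, and 764 and 619, with 694 and 282 shared and an authors' share of 90.1%.

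Leaving out 1 library gave 61 to 1296 higher and 24 to 649 lower in MCF-10A, 792 to 1673 and 461 to 1060 in SK-BR-3, and 88 to 519 and 48 to 516 for the difference. Between the DMSO groups it gave 4480 to 4848 and 4376 to 4708. Shared genes ranged from 14 to 367 and from 6 to 101, the authors' shares from 5.47% to 70.0% and from 54.0% to 91.3%, and the correlation of the lines from 0.233 to 0.311. Of the named genes called, 18 of 83 in MCF-10A, 67 of 114 in SK-BR-3 and 19 of 58 for the difference stayed called whichever library was left out, with 0 changes of sign. Over all settings the values of called named genes and the panel were the same in 6184 cases, lost their call in 1453, gained it in 21, moved in 29 and reversed in 6, and gene lists kept their call in 938 cases and lost it in 162. Every called list of the DATS comparisons was lost with an estimated correlation, with or without the block. Leaving out some 1 library ended the call of the AP-1, hypoxia, ERBB family and FOXO lists in MCF-10A, of the hydrogen sulfide, metallothionein, DNA repair and hypoxia lists in SK-BR-3, and of the AP-1, interferon, fatty acid and proteasome lists for the difference. Removing the trends of GC content and gene length ended the AP-1 call in MCF-10A, the hydrogen sulfide and hypoxia calls in SK-BR-3, and the AP-1, fatty acid and ERBB2 amplicon calls for the difference. In camera it added heat shock (adjusted p = 0.0484) and oxidative phosphorylation (0.0438) in MCF-10A and endothelial markers in SK-BR-3 (0.0301). For the difference it added metallothioneins (0.0144) and the ERBB family (0.0141). With the block as well, heat shock was not called (0.0504). These added calls were not tried with an estimated correlation in that fit. Genes near the filter of 1 FPKM rest on few reads, which limits their precision. The difference of responses reversed in edgeR and DESeq2 for CCL22 (−1.71 and −1.14), CDH5 (−3.78 and −3.24) and PTGS2 (2.99 and 2.31), each at 0 FPKM in a DMSO group.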

Other observations

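RPL26, a protein of the large ribosomal subunit (chromosome 17, 8377516 to 8383250), fell in MCF-10A from 19.9 ± 0.219 to 11.2 ± 2.39 FPKM (-0.79 ± 0.17, adjusted p = 0.0256) and in SK-BR-3 from 19.4 ± 1.37 to 11.4 ± 2.96 FPKM (-0.75 ± 0.17, adjusted p = 0.0138). In the list of cytosolic ribosomal proteins 1 of 55 genes was lower in each line, with 1 higher in SK-BR-3 with the replicate block. In GENCODE 29 the gene overlaps a protein-coding gene on its own strand and a gene on the other strand, and the sharing of reads among them is uncertain.

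CDH5, an adherens junction protein of endothelium, rose in SK-BR-3 from 11.8 ± 2.88 to 25.3 ± 4.42 FPKM (1.04 ± 0.15, adjusted p = 0.00139) and was near 0 FPKM in MCF-10A. In SK-BR-3 the Notch ligand JAG1 rose (0.85 ± 0.23, adjusted p = 0.0265) and the aldehyde dehydrogenase ALDH1A1 fell (-0.87 ± 0.16, adjusted p = 0.00508), within a list of stem cell and Notch genes of which 3 of 18 were higher and 1 lower, or 6 and 2 with the replicate block. ALDH1A3, an enzyme of retinoic acid synthesis, rose in MCF-10A from 32.4 ± 9.43 to 80.5 ± 11.9 FPKM (1.32 ± 0.23, adjusted p = 0.0116). FBXO32, a ubiquitin ligase subunit and FOXO target, rose in MCF-10A (0.73 ± 0.18, adjusted p = 0.0392) and in SK-BR-3 (0.73 ± 0.18, adjusted p = 0.0183). LAMB3, a laminin chain, rose in SK-BR-3 (1.11 ± 0.29, adjusted p = 0.0224) and had 1.01 ± 0.29, adjusted p = 0.059 in MCF-10A, where it passed with the replicate block (adjusted p = 0.008). Leaving out some 1 library ended the calls of RPL26, ALDH1A3 and FBXO32 in MCF-10A and of JAG1, FBXO32 and LAMB3 in SK-BR-3.

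Mitochondrial transcripts made up 7.98% of the reads in SK-BR-3 DATS library 2, against 5.74% and 5.12% in libraries 1 and 3.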
